A study of Mus musculus with 30 samples.

How the data were processed

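RNA was extracted from the ascending and the descending colon of female mice and, per the labels' protocols, 1 ug of total RNA was depleted of ribosomal RNA, made into libraries with the Kapa Hyper Prep kit with RiboErase, and sequenced as single reads of 50 nt on an Illumina HiSeq instrument. The 30 libraries comprise 7 controls and 8 mutants per region, from 3 cages. The deposited table holds FPKM (fragments per kilobase of gene and per M mapped reads) computed by the authors, with 2 decimals. Per the submitters' processing notes, bcl2fastq, STAR and DESeq2 were used with the GRCm38 (mm10) mouse genome, and the gene counter, annotation release, gene length and gene filter are not given in the sources used here. Of the identifiers in the table, 14472 were found in the GENCODE M21 annotation, 14469 were protein-coding and 0 were mitochondrial. Positions are from that annotation.

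The files give no read counts. Because an FPKM of a short gene moves in steps set by its length and by depth, the depth of each library was estimated from the spacing of its low values, over genes of 300 to 2500 nt and up to 3 steps. The estimates ran from 1.43 to 8.88 M reads, and 73.8 to 83.7% of the low values lay within 0.2 of a step. The step of each library was the one that best fitted these same values, so that share is no independent check of the depth. The depths are estimates and entered no test. The precision of each value comes from the spread between libraries.

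Groups follow the sample labels: region, genotype and cage. Each value was transformed to log2(FPKM + 1), genes with a mean of at least 0.5 FPKM over the libraries of a fit were kept, and each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on the mean). Mutants were compared with controls in each region with cage as a covariate, the difference between the regional effects was tested as an interaction over all 30 libraries, and regions were compared in the 14 controls with cage as a covariate. Genotype effects that depend on cage were tested with a moderated F test in each region. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparison of regions in the 16 mutant libraries was added after seeing the data.

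Gene lists, 35 in number, were fixed before the data were examined, covering O-glycan synthesis and extension, goblet cells, mucins, defence, epithelial cell types, proliferation, metabolism, patterning, clock, immune cells and the other cells that a piece of colon can hold. A list was tested when at least 5 members were kept, so that lists of B cells and follicles, plasma cells, mast cells and pancreas were tested in no comparison. Blood and neutrophil lists were not tested in the ascending colon, and the T cell list was not tested in the descending colon. Lists were tested with camera (limma) at its preset correlation of 0.01, with camera at an estimated correlation, and with the rotation test fry, each with Benjamini-Hochberg adjustment over the lists of a comparison. Members were counted past the threshold over all genes and adjusted over the list alone.

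Genes to be named were chosen by a rule written before the data were examined. The rule takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 FPKM and the same direction in all 3 cages, leaving out unnamed predicted genes and immunoglobulin or T cell receptor segments. To these it adds B3gnt6, C1galt1 and up to 4 members of each list with the smallest adjusted p, and, for the cage-dependent effects, the 5 genes with the smallest adjusted p. Genes named outside the rule are given as chosen after their values were seen, and a few genes that the rule takes are not reported here. For the ascending colon without cage B the same rule was applied to cages A and C.

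The fits were tested on simulated data with the dimensions and gene-wise noise of each comparison and 200 changed genes. The noise was drawn independently for each gene, without correlation between genes and without deviating libraries. Recovery in the real data can therefore be lower than the shares given here. Log2 changes of 0.5, 1 and 2 were recovered in 40.3, 88.1 and 98.5% of cases for the ascending colon and in 31.3, 88.1 and 98.5% for the descending colon. The interaction recovered 10.4, 70.1 and 97.0%, and the comparison of regions 25.4, 89.6 and 98.5%, with 9, 4, 6 and 12 false calls in the 4 comparisons in the order given.

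Alternatives fixed in advance were a pseudocount of 0.1, no filter or a mean of at least 2 FPKM, median-of-ratios scaling, quantile normalization, robust moderation, array quality weights, leaving out each cage or each library, no cage covariate, 1 fit of all 30 libraries, and a replicate block from the numbers in the titles. Leaving out ascending control B1 and descending control A2 together was added after seeing the data, as were the list tests with each library left out. Permutations reassigned genotypes within cages. The permutation tests of 5 lists of non-epithelial cells used log2(FPKM + 0.1), and were repeated on log2(FPKM + 1) after seeing the data. Raw reads were not analysed here.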

Results

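Total RNA depleted of ribosomal RNA was sequenced from 30 pieces of mouse colon as single reads of 50 nt. The pieces came from the ascending and the descending colon of female controls and of littermates with deletions aimed at enzymes that build cores of the main O-glycans, the sugar chains that coat mucins. C1galt1 makes the core 1 O-glycan, and B3gnt6, also called C3GnT, makes the core 3 O-glycan. The mutants carried floxed C1galt1, a tamoxifen-inducible Cre recombinase driven by the Villin promoter of the gut epithelium, and no functional B3gnt6. Mice received 0.5 mg tamoxifen a day, about 20 mg/kg, for 5 days, and the protocol gives analysis 5 or 10 days later without saying which time applies to which library. Each region had 7 control and 8 mutant libraries from 3 cages, all with the same microbiota. Cage A held mice of 3.4 months labelled 'C57BL/6 Background', and cages B and C held mice labelled 'Mixed BL/6-129SvJ', aged 2.6 and 3.2 months. Cage A therefore differs from the others in cage, strain and age at once, whereas cages B and C share the strain label and differ in cage and age. Values are FPKM as deposited. The files give no read counts, so the depth was estimated from the steps between the low values of each library. It ranged from 3.40 to 6.48 M reads in ascending controls, 1.43 to 7.76 M in ascending mutants, 3.12 to 8.79 M in descending controls and 6.48 to 8.88 M in descending mutants. The lowest estimates were those of the 3 ascending mutants of cage A, at 1.43 to 1.59 M reads.

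C1galt1 (ENSMUSG00000042460.5; GRCm38 chromosome 6, 7844842 to 7875687) was measured at 21.5 to 45.7 FPKM in the 7 ascending controls and 18.3 to 34.3 in the 8 ascending mutants. In the descending colon the ranges were 28.0 to 38.7 in controls and 14.6 to 36.7 in mutants. The ascending means were 35.3 ± 9.44 (SD, n = 7) and 26.7 ± 6.64 (n = 8), and the descending means 32.9 ± 3.47 and 28.2 ± 7.15. The log2 difference was -0.36 ± 0.13 (SE) in the ascending colon (limma adjusted p = 0.348) and -0.28 ± 0.16 in the descending colon (adjusted p = 0.999). Cage means were lower in mutants in all 3 cages of each region, but not every cage separated the genotypes. Ascending mutant C3, at 27.6 FPKM, exceeded both controls of its cage (23.8 and 21.5). The descending mutants of cage A, at 30.9 to 36.7 FPKM, lay between its 2 controls (30.4 and 38.7). Without cage B the ascending difference was -0.18. FPKM sum reads over the whole gene and over epithelial and other cells, and the deleted part of the gene is not given in the sources used here. B3gnt6 (ENSMUSG00000074004.3; GRCm38 chromosome 7, 98192417 to 98199481) reached 9.52 and 19.5 FPKM in ascending controls B1 and B2 (replicates 1 and 2 of cage B), and was between 0.11 and 0.60 in the other 5 ascending controls. It was at or below 0.53 FPKM in all 8 ascending mutants, at or below 0.43 in descending controls and at or below 0.06 in descending mutants. Most controls of both regions were therefore near the floor for this gene, as the mutants were, so it says little about the genotype labels except in ascending controls B1 and B2. Ascending control B3 of the same cage was at 0.11 FPKM. The estimated depth of B1, B2 and B3 was alike (3.83, 3.40 and 3.65 M reads), so depth does not account for the gap between them. Whether the controls with low values carried functional B3gnt6 cannot be told from these values. Gcnt1, which branches core 1 into core 2, was 12.8 ± 3.58 FPKM in ascending controls and 9.08 ± 4.18 in mutants (log2 difference -0.63 ± 0.23, adjusted p = 0.345; -0.22 without cage B).

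**Figure D1:**
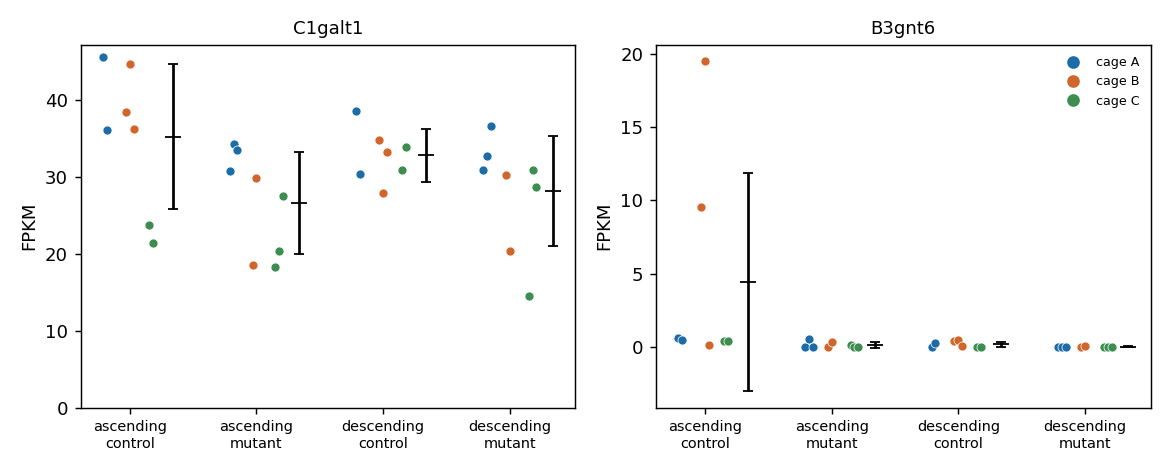
FPKM of C1galt1 (left) and B3gnt6 (right) in each of the 30 libraries, by region and genotype; points are libraries coloured by cage, and bars are the mean and SD of the group. C1galt1 spans 18.3 to 34.3 FPKM in ascending mutants and 21.5 to 45.7 in ascending controls, and B3gnt6 is above 1 FPKM in 2 libraries, both ascending controls of cage B.

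In the ascending colon 8 mutant libraries were compared with 7 control libraries, with cage as a covariate. The contrast is of labelled genotypes: glycans were not measured in these data, and B3gnt6 RNA was near the floor in most controls. Cell division genes were higher in mutants as a group: all 25 members of the proliferation list lay above 0, with a median log2 difference of 0.41. Kif20a, a mitotic kinesin, went from 3.57 ± 1.20 FPKM in controls (SD, n = 7) to 6.86 ± 3.00 in mutants (n = 8, log2 difference 0.74 ± 0.18, SE, adjusted p = 0.214), and Mki67, the Ki-67 antigen of dividing cells, from 21.2 ± 4.59 to 29.4 ± 8.67 (0.46 ± 0.13, adjusted p = 0.273). Nusap1, a spindle protein, had a log2 difference of 0.52 ± 0.12 and the cyclin Ccnb2 of 0.62 ± 0.18. All 21 members of the cholesterol synthesis list were higher as well, with a median of 0.40. Cyp51, the lanosterol demethylase, was 15.5 ± 3.85 FPKM in controls and 25.3 ± 4.02 in mutants (0.69 ± 0.14, adjusted p = 0.214). Mvd, the mevalonate diphosphate decarboxylase of the pathway, was 9.79 ± 4.24 and 16.1 ± 2.07 (0.70 ± 0.17). No member of either list passed the threshold over all genes, and adjusted over the list alone 12 of 25 and 12 of 21 passed. The lists passed camera with its preset correlation (adjusted p = 1.86e-20 and 5.00e-18); with an estimated correlation the adjusted p was 0.147 for each. The rotation test fry passed both (adjusted p = 0.0466).

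Markers of differentiated, absorptive colonocytes were higher in 15 of 21 cases, with a median of 0.28 (camera adjusted p = 8.96e-06, and adjusted p = 0.286 with an estimated correlation), and 3 passed adjusted over the list alone against 0 over all genes. Car1, a carbonic anhydrase abundant in the proximal colon, was 4800.3 ± 1814 FPKM in controls and 10051 ± 1846 in mutants (log2 difference 1.13 ± 0.26). The brush border phosphatase Alpi had a log2 difference of 0.97 ± 0.23, and the fatty acid binding protein Fabp2 was 501 ± 229.8 and 936 ± 273 (0.93 ± 0.25). Of the xenobiotic response list, 10 of 14 members were higher (median 0.35, camera adjusted p = 8.58e-07, and adjusted p = 0.147 with an estimated correlation), 6 of them past the threshold adjusted over the list alone. The glutathione transferase Gsta1 was 17.8 ± 14.5 FPKM in controls and 40.4 ± 17.0 in mutants (1.39 ± 0.38), and the cytochrome P450 gene Cyp2c65 was 116 ± 30.9 and 179.8 ± 46.6 (0.54 ± 0.15). In the list of PPAR-alpha and fatty acid oxidation genes 15 of 18 were higher, with a median of 0.16 (adjusted p = 0.00140, and adjusted p = 0.396 with an estimated correlation). That call ended without ascending control C1 (adjusted p = 0.114) and with quantile normalization (median 0.15, adjusted p = 0.0556). Its member Angptl4, a lipoprotein lipase inhibitor, went the other way (-0.72 ± 0.20). The colonocyte median was 0.11 without ascending control C2, and the PPAR-alpha median 0.07 without ascending control B1 and 0.09 without ascending control C1. All 14 stem cell markers were lower, with a median of -0.19 (adjusted p = 0.00809, and adjusted p = 0.473 with an estimated correlation; 0.126 without ascending mutant B1). Lgr5, the crypt base receptor, was 1.17 ± 0.274 FPKM in controls and 0.730 ± 0.246 in mutants (-0.35 ± 0.12).

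Markers of the tissue under the epithelium were lower in ascending mutants. In the fibroblast and matrix list 15 of 16 members were lower, with a median of -0.78 (camera adjusted p = 2.32e-08, and adjusted p = 0.194 with an estimated correlation), and 10 passed adjusted over the list alone against 0 over all genes. The collagen gene Col1a1 was 9.67 ± 5.12 FPKM in controls and 3.34 ± 1.79 in mutants (log2 difference -1.29 ± 0.37), and Sparc, a matrix glycoprotein, 14.5 ± 6.30 and 5.39 ± 3.29 (-1.28 ± 0.31). All 10 macrophage markers were lower (median -0.64, adjusted p = 5.88e-06, and adjusted p = 0.194 with an estimated correlation), 5 of them past the threshold adjusted over the list alone. The lysozyme gene Lyz2 of myeloid cells was 56.8 ± 47.8 FPKM and 17.6 ± 19.0 (-1.87 ± 0.58), with -4.07, -0.28 and -1.26 in cages A, B and C. By cage the mean effect was -1.19, -0.63 and -0.49 for the fibroblast list and -1.52, -0.27 and -0.49 for the macrophage list. Both were largest in cage A, whose ascending mutants had the lowest estimated depth. Without ascending control B1 they were -0.38 and -0.10 in cage B. The list of enteric neurons and glia instead fell least in cage A (-0.21, against -0.62 and -0.75). Smooth muscle genes were lower in 12 of 13 cases (median -1.03, adjusted p = 0.00106, and adjusted p = 0.473 with an estimated correlation), among them the desmin gene Des at 12.3 ± 16.4 and 2.31 ± 1.40 FPKM. The mean effect on the smooth muscle list was -0.28, -1.05 and -0.87 in cages A, B and C, and -0.24 in cage B without ascending control B1, without which the median was -0.68 (adjusted p = 0.0429). For its 12 members with a mean of at least 1 FPKM the effect had an exact permutation p of 0.104. All 6 markers of enteric neurons and glia were lower (median -0.48, adjusted p = 7.57e-04, and adjusted p = 0.389 with an estimated correlation), 4 of them past the threshold adjusted over the list alone. Uchl1, a neuronal ubiquitin hydrolase, was 2.73 ± 1.72 and 0.601 ± 0.684 FPKM. The neuronal median was -0.31 (adjusted p = 0.0302) without ascending control B1. The 5 endothelial markers had a median of -0.24 (adjusted p = 0.0229, and adjusted p = 0.277 with an estimated correlation). That call ended without ascending control A2 (adjusted p = 0.0648), ascending control B1 (0.108) or ascending mutant B1 (0.126), and with quantile normalization (median -0.10, adjusted p = 0.182). The endothelial median was -0.38 without ascending control C2. Ascending control B1 held more smooth muscle RNA than the other ascending controls, with the myosin gene Myh11 at 43.4 FPKM against a group mean of 11.4 ± 14.6.

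Immune genes were lower too. All 11 T cell markers lay below 0 (median -0.46, adjusted p = 0.00239, and adjusted p = 0.396 with an estimated correlation; 0.110 without ascending mutant B1), with Cd8a, the co-receptor of cytotoxic T cells, at 3.75 ± 1.26 FPKM in controls and 2.39 ± 0.949 in mutants. All 24 genes of interferon-gamma response and antigen presentation were lower, with a median of -0.48 (adjusted p = 8.61e-07, and adjusted p = 0.396 with an estimated correlation). The class II gene H2-Aa was 169.8 ± 126 and 94.0 ± 99.6 FPKM (log2 difference -0.94 ± 0.37). Of the interferon-stimulated genes 19 of 21 were lower, with a median of -0.47 (adjusted p = 5.63e-04, and adjusted p = 0.609 with an estimated correlation), and the antiviral gene Oas2 was 28.4 ± 24.1 and 11.1 ± 5.88 FPKM. That call ended without ascending control B1 (adjusted p = 0.0928), whose Isg15 was 517.9 FPKM, and without ascending mutant B1 (0.18). The interferon-stimulated median was -0.29 without ascending control B1 and -0.26 without ascending mutant B1, and the interferon-gamma median -0.31 without ascending mutant B1. The interferon falls were smaller without cage B, where the log2 difference of H2-Aa was -0.26, and the medians were -0.29 for the interferon-gamma list and -0.17 for the interferon-stimulated genes. No member of these 3 lists passed over all genes or adjusted over the list alone.

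The mucus genes themselves showed no such shift. The goblet cell list had 9 members higher and 14 lower (median -0.04, camera adjusted p = 0.389), the O-glycan core list 6 and 9 (median -0.09, 0.675) and the list of glycan extension and capping 9 and 16 (-0.03, 0.882). The goblet list's mean was 0.06, on the other side of 0 from its median. The transmembrane mucins had a median of -0.30 (adjusted p = 0.0927), passed with quantile normalization (median -0.26, adjusted p = 0.00655), and Muc1, at 2.71 ± 2.75 FPKM in controls and 0.756 ± 0.751 in mutants, passed adjusted over the list alone. Antimicrobial and oxidative defence genes had a median of 0.17 (adjusted p = 0.0875), the unfolded protein response -0.06 (0.483), junctions 0.01 (0.293), tuft cells -0.09 (0.685) and enteroendocrine cells -0.18 (0.184). The medians of the remaining lists, with their camera adjusted p, were bile acid handling 0.00 (0.263), ion transport -0.05 (0.870), posterior patterning -0.15 (0.785), circadian clock -0.09 (0.870), adipocytes -0.66 (0.118) and immediate early genes 0.06 (0.249).

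Gene by gene, limma called 0 of 12178 genes in the ascending colon, with a lowest adjusted p of 0.212. At an unadjusted p under 0.05 it found 1396 genes, 421 higher and 975 lower, where 608.9 would be met by chance. The count depended on the libraries and weights used: without cage B 652 genes passed, 259 higher and 393 lower, with array quality weights 746 (288 higher, 458 lower), and without ascending mutant B1 170 (88 higher, 82 lower). In the fit of all 30 libraries 3 genes passed, namely Abca1 (log2 difference -0.77), Scg3 (-0.65) and Esr1 (0.89), chosen after their values were seen. Leaving out ascending control B1, B2 or B3 gave 1 gene each, Abca1 (-0.83), Esr1 (1.01) and Stmn3 (-1.22). Of the 652 genes, 411 also passed in the same direction with array quality weights, and 213 (32.7%) had the same sign in cage B. Among the 652 genes the goblet cell gene Spink4 (1.66), Gsta1 (1.86) and Car1 (1.38) were higher, and Lyz2 (-2.67), the fibronectin gene Fn1 (-2.46) and Col1a1 (-1.65) lower, on the log2 scale in cages A and C.

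**Figure D2:**
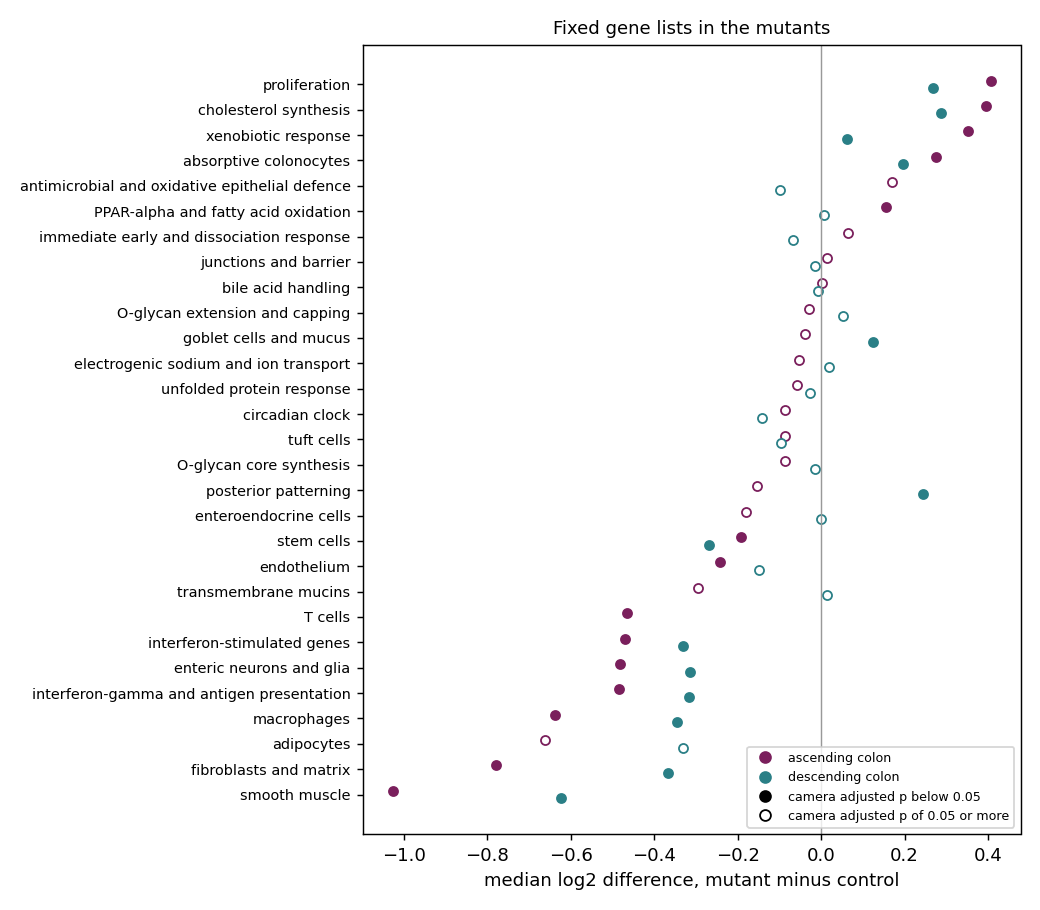
Median log2 difference (mutant minus control, log2 of FPKM plus 1) of each fixed gene list tested in the ascending colon, with its value in the descending colon where tested there; filled points are lists with a camera adjusted p below 0.05 at the preset correlation. The neutrophil and blood lists, tested in the descending but not in the ascending colon, are not shown. Proliferation and cholesterol synthesis lie at 0.41 and 0.40 in the ascending colon, and smooth muscle and fibroblast lists at -1.03 and -0.78.

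**Figure D3:**
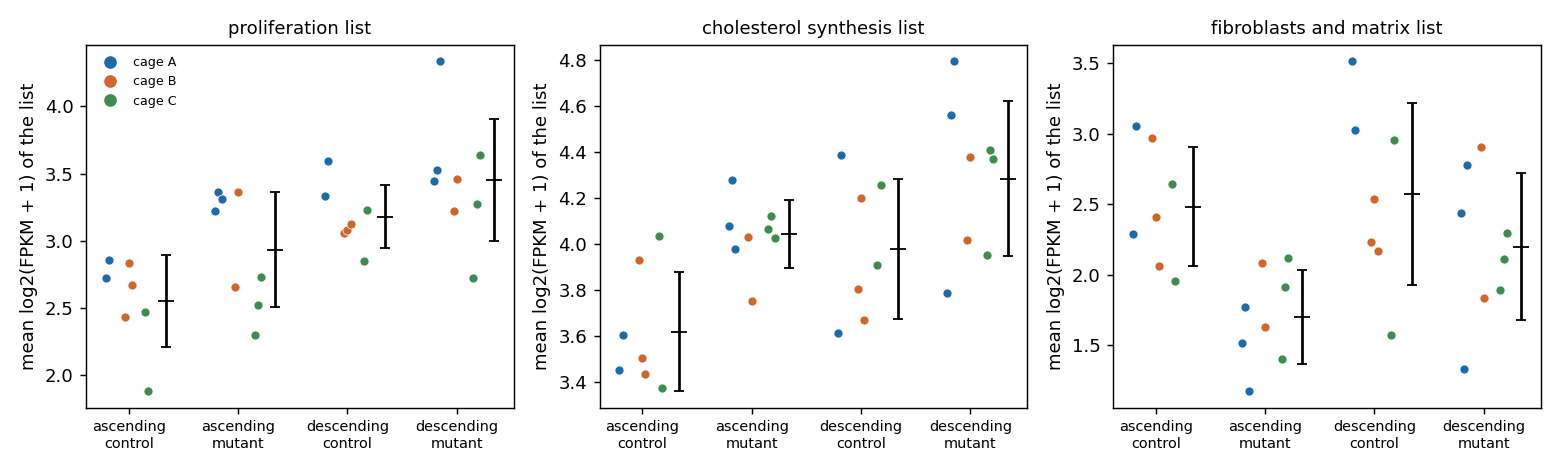
Mean log2(FPKM + 1) of the members of 3 lists in each library, by region and genotype; points are libraries coloured by cage, and bars are the mean and SD of the group. In the ascending colon the proliferation score was higher in mutants in each cage, by 0.51, 0.36 and 0.34 in cages A, B and C.

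The descending colon of the same groups was compared in the same way. The proliferation list had 21 of 25 members higher, with a median of 0.27 (camera adjusted p = 3.79e-14, and adjusted p = 0.279 with an estimated correlation). Mki67 was 41.5 ± 8.44 FPKM in controls (SD, n = 7) and 59.8 ± 15.8 in mutants (n = 8, log2 difference 0.47 ± 0.16, SE), and Ccnb2 16.1 ± 2.60 and 24.0 ± 7.71 (0.52 ± 0.15). Cholesterol synthesis genes were higher in 20 of 21 cases (median 0.29, adjusted p = 1.03e-13, and adjusted p = 0.279 with an estimated correlation). Hmgcs1, the HMG-CoA synthase at the start of the pathway, was 59.6 ± 13.0 and 86.1 ± 30.2 FPKM (0.46 ± 0.24), and 1 of the 21 members passed adjusted over the list alone, against 0 over all genes. Absorptive colonocyte markers were higher in 19 of 21 cases (median 0.20, adjusted p = 1.08e-05, and adjusted p = 0.0825 with an estimated correlation). The xenobiotic list had a median of 0.06 (adjusted p = 5.19e-04, and adjusted p = 0.0855 with an estimated correlation), with the glutathione transferase gene Gstm1 at 77.2 ± 24.6 and 132 ± 59.1 FPKM. Goblet cell genes were higher in 16 of 23 cases (median 0.12, adjusted p = 0.00548, and adjusted p = 0.484 with an estimated correlation). Posterior patterning genes were higher in 10 of 15 (median 0.24, adjusted p = 0.0120, and adjusted p = 0.304 with an estimated correlation). Both of these calls ended under quantile normalization (medians 0.11 and 0.21, adjusted p = 0.254 and 0.0895). The goblet call also ended without descending control A1 (adjusted p = 0.108), descending mutant A3 (0.145) or C1 (0.0628), and the patterning call without descending control A2 (0.839) or mutant C1 (0.165) and with median-of-ratios scaling (median 0.28, adjusted p = 0.0538). Medians also moved by over 1.5 times without 1 library. Cholesterol synthesis was 0.18 without descending control A1 and 0.19 without mutant B2. Goblet cells were 0.06 without control A1, 0.05 without mutant A3, 0.27 without mutant A2 or control C2 and 0.20 without mutant C3. Patterning was -0.05 without control A2 and 0.15 without mutant A1. The xenobiotic median was from 0.02 to 0.23 in 11 such omissions, all but those of descending mutants A1, A2 and C3 and control B3.

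On the lower side, 12 of 13 stem cell markers were lower (median -0.27, adjusted p = 2.37e-05, and adjusted p = 0.323 with an estimated correlation). Lgr5 was 2.09 ± 1.22 FPKM in controls and 0.834 ± 0.281 in mutants (-0.76 ± 0.18), past the threshold adjusted over the list alone but not over all genes. All 13 smooth muscle genes (median -0.62, adjusted p = 0.00151, and adjusted p = 0.484 with an estimated correlation) and all 8 markers of enteric neurons and glia (median -0.32; 2.05e-04, and adjusted p = 0.329 with an estimated correlation) were lower. Fibroblast genes were lower in 14 of 16 cases (median -0.37, adjusted p = 8.27e-04, and adjusted p = 0.484 with an estimated correlation), with Col1a1 at 14.2 ± 8.38 and 8.09 ± 3.63 FPKM. The smooth muscle and fibroblast calls ended without descending control A1 (adjusted p = 0.0728 and 0.204) or descending mutant B2 (0.102 and 0.0515). Interferon-stimulated genes had a median of -0.33 (adjusted p = 9.34e-05, and adjusted p = 0.484 with an estimated correlation; 0.361 without descending control A2), and interferon-gamma and antigen presentation genes of -0.32 (adjusted p = 1.71e-04, and adjusted p = 0.484 with an estimated correlation). Macrophage markers had a median of -0.34 (adjusted p = 0.0424, and adjusted p = 0.484 with an estimated correlation), a call that ended without any of 9 libraries (0.0516 to 0.389): descending controls A1, A2, B1 and C2 and mutants A1, A2, A3, C2 and C3. Neutrophil genes had a median of -0.31 (adjusted p = 0.00882, and adjusted p = 0.347 with an estimated correlation), a call that ended without descending controls A1, B1 or C1 or mutants A3 or C1 (0.0556 to 0.289). Their member S100a8, a calprotectin subunit, was 1.26 ± 1.17 and 0.191 ± 0.144 FPKM and passed adjusted over the list alone. Here too medians moved by over 1.5 times without 1 library. Without descending control A1 they were -0.41 for smooth muscle, -0.21 for fibroblasts and -0.18 for neutrophils. Without control A2 they were -0.13 for stem cells, -0.12 for interferon-stimulated genes, -0.08 for macrophages and -0.15 for neutrophils. Smooth muscle was -0.998 without control B1, fibroblasts -0.59 without mutant B1 and neutrophils -0.20 without mutant A3. Interferon-stimulated genes were -0.18 without control B2, and interferon-gamma genes -0.20 without control B2 or mutant B2. No member of a list passed over all genes. Lists that did not pass camera were, with median and adjusted p, O-glycan core synthesis -0.02 (0.834), glycan extension 0.05 (0.143), transmembrane mucins 0.01 (0.685), defence -0.10 (0.844), tuft cells -0.10 (0.841), enteroendocrine cells -0.00 (0.327), unfolded protein response -0.03 (0.867), junctions -0.01 (0.774), PPAR-alpha 0.01 (0.867), bile acid handling -0.01 (0.223), ion transport 0.02 (0.977), circadian clock -0.14 (0.861), endothelium -0.15 (0.203), blood 0.01 (0.658), immediate early genes -0.07 (0.327) and adipocytes -0.33 (0.0927), the last of which passed with median-of-ratios scaling (median -0.30, adjusted p = 0.047). The median, mean and test of the core, transmembrane mucin, defence, enteroendocrine, junction, PPAR-alpha, bile acid, ion transport, clock and blood lists did not all have the same sign. By gene, limma called 0 of 12219 genes (lowest adjusted p 0.605), with 267 at an unadjusted p under 0.05 where 610.95 would be met by chance. With array quality weights 1 gene passed, the phospholipase gene Pla2g3 (log2 difference 0.87, chosen after its value was seen).

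Whether the mutant effect differed between the regions was tested as an interaction over all 30 libraries. Of the T cell markers, all 10 had a more negative effect in the ascending colon, with a median log2 difference between effects of -0.41 (camera adjusted p = 1.58e-05, and adjusted p = 0.423 with an estimated correlation). Cd8a was 3.75 ± 1.26 FPKM in ascending controls (SD, n = 7) and 2.39 ± 0.949 in ascending mutants (n = 8), but 0.159 ± 0.0799 and 0.171 ± 0.0934 in the descending colon, where its level was near the floor. Fewer than 5 T cell markers were kept in the descending colon, so the list was not tested there, and markers near the floor cannot fall on this scale. The T cell difference therefore largely restates the effect in the ascending colon. Macrophage (-0.43), fibroblast (-0.40), blood (-0.91), posterior patterning (-0.37), interferon-gamma (-0.24) and enteroendocrine (-0.18) lists also had a more negative effect in the ascending colon. The proliferation (0.14), cholesterol synthesis (0.11), PPAR-alpha (0.15), xenobiotic (0.15) and immediate early (0.20) lists had a more positive effect there. These 12 of 31 lists passed camera with the preset correlation, 0 passed with an estimated correlation (lowest adjusted p = 0.423) and 0 passed fry. The number of lists fell to 7 without descending control A2 and to 7 without ascending control A2. The T cell call held when each library was left out in turn. The macrophage call ended without ascending control A2 (adjusted p = 0.0975), the patterning call without descending control A2 (0.529), and the proliferation call without ascending mutant B2 (0.061) or ascending control C2 (0.0682). The blood call ended without descending control A2 (0.0662), ascending control A2 (0.0975) or ascending mutant B2 (0.0634). The PPAR-alpha call ended in 4 of the 30 omissions (0.0507 to 0.168), the fibroblast call in 5 (0.0662 to 0.267), the enteroendocrine call in 8 (0.0547 to 0.233) and the interferon-gamma call in 10 (0.0536 to 0.839). The immediate early call ended in 13 (0.0603 to 0.427), the cholesterol call in 14 (0.0517 to 0.343) and the xenobiotic call in 18 (0.0507 to 0.258). The cholesterol call also ended with quantile normalization (median 0.10) and the immediate early call with quantile normalization or no cage covariate (0.18 and 0.17). The xenobiotic call ended with a pseudocount of 0.1, quantile normalization or no cage covariate (0.14, 0.07 and 0.16), and the proliferation and interferon-gamma calls ended with no cage covariate (0.10 and -0.18). Medians moved by over 1.5 times in this number of omissions, with the medians then met: cholesterol synthesis 15 (0.04 to 0.26), xenobiotic 6 (0.04 to 0.23), PPAR-alpha 5 (0.03 to 0.25), proliferation 5 (0.07 to 0.28), fibroblasts 4 (-0.62 to -0.16), interferon-gamma 4 (-0.38 to -0.01), enteroendocrine cells 3 (-0.28 to -0.09), immediate early genes 3 (0.08 to 0.12), blood 2 (-1.40 to -0.49) and patterning 2 (-0.69 to -0.15). The remaining 19 lists had adjusted p from 0.0695 to 0.967, among which transmembrane mucins passed with a pseudocount of 0.1, quantile normalization or no cage covariate (medians -0.24, -0.30 and -0.35), and enteric neurons and glia with a pseudocount of 0.1, median-of-ratios scaling or no cage covariate (medians -0.50, -0.21 and -0.20). Pdk4, the kinase that restrains pyruvate dehydrogenase, was 13.8 ± 5.10 and 17.6 ± 6.37 FPKM in ascending controls and mutants and 1.11 ± 1.01 and 0.477 ± 0.427 in descending ones (difference 0.93 ± 0.29, adjusted p = 1.000). By gene, limma called 0 of 12353 genes (198 at an unadjusted p under 0.05, where 617.65 would be met by chance). C1galt1 had a difference between effects of -0.08 ± 0.21.

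The regions themselves differed widely, as shown by comparing 7 ascending with 7 descending control libraries. Some mucus genes were far higher in the ascending colon. Muc2, the main gel-forming mucin, was 5039 ± 2533 FPKM there (SD, n = 7) and 775 ± 605 in the descending colon (n = 7, log2 difference 2.74 ± 0.36, SE, adjusted p = 6.52e-05), and Guca2a, which encodes guanylin, 2889 ± 986 and 442 ± 396 (2.96 ± 0.38; 4.57e-05). Gcnt3, which makes core 2 and core 4 branches, was 237 ± 44.3 and 26.9 ± 5.54 FPKM (3.10 ± 0.14; 1.33e-08), whereas B3gnt7 (-5.72 ± 0.31; 5.76e-08) and Fut9 (-2.77 ± 0.24; 1.90e-06), which extend and fucosylate glycans, were higher in the descending colon. C1galt1 did not pass (0.06 ± 0.13, adjusted p = 0.766). B3gnt6 did not pass either (1.24 ± 0.52; 0.0745), and it passed with a pseudocount of 0.1 (log2 difference 2.57, adjusted p = 0.0255). The goblet list had 6 members higher and 1 lower in the ascending colon, the core list 5 and 1, and the extension list 5 and 9 (camera adjusted p = 0.0101, 1.72e-04 and 0.589, adjusted p = 0.654, 0.355 and 0.817 with an estimated correlation). The goblet median of 0.19 was 0.41, 0.12 and 0.28 without ascending control B1, B2 or C1, and 0.39, 0.31 and 0.35 without descending control A2, B3 or C2. The goblet call ended under quantile normalization, with a median of 0.11 (adjusted p = 0.131).

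The largest differences toward the ascending colon were the antimicrobial lectin genes Reg3b (7.68 ± 1.05) and Reg3g (5.10), Sptssb (6.41), Isx (6.19), Tmigd1 (6.10), Fabp2 (5.91), Apol10a (5.86), Prap1 (5.73), the bile acid exporter subunit Slc51a (5.17) and Cyp4b1 (5.12). Those toward the descending colon were Sval1 (-7.78 ± 0.54), the proton pump gene Atp12a (-7.30), Tgm3 (-7.27), Hoxb13 (-7.20), Ly6g (-6.31), Mptx1 (-6.24), Hoxd13 (-5.72), B3gnt7 (-5.72), Slc37a2 (-4.98) and Sycn (-4.85). The rule that chose these 20 required the same sign in each cage. Hoxb13, a marker of the hindgut's end, was 0.726 ± 1.69 FPKM in ascending and 229 ± 92.2 in descending controls, and Hoxd13 was listed at 0 in every ascending control. The neurotensin gene Nts was 22.9 ± 13.7 and 0.0514 ± 0.102 FPKM, and the hormone gene Insl5 was 2.60 ± 4.27 and 74.0 ± 47.5.

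All 21 interferon-stimulated genes were higher in the ascending colon, each past the threshold, with a median of 2.04 (camera adjusted p = 2.61e-12, and adjusted p = 0.355 with an estimated correlation). Ifit1, an antiviral effector, was 80.6 ± 65.8 and 5.69 ± 6.61 FPKM (adjusted p = 2.28e-04). Of 10 T cell markers 9 were higher (median 1.19, adjusted p = 2.32e-08, and adjusted p = 0.210 with an estimated correlation), among them the granzyme gene Gzmb at 5.88 ± 2.41 and 0.104 ± 0.146 FPKM. The xenobiotic list, with 9 members higher and 1 lower (median 1.31), passed with the preset and the estimated correlation (adjusted p = 2.32e-08 and 0.0333), and its member Cyp2c65 was 116 ± 30.9 and 3.82 ± 4.02 FPKM. Lists of bile acid handling (median 1.14), interferon-gamma (0.66), tuft cells (0.62), adipocytes (0.69), PPAR-alpha (0.40), absorptive colonocytes (0.36) and enteroendocrine cells (0.28) also passed toward the ascending colon with the preset correlation. None of these 7 passed with an estimated correlation (adjusted p = 0.0982, 0.355, 0.355, 0.496, 0.355, 0.355 and 0.355). The colonocyte call ended under quantile normalization (median 0.32, adjusted p = 0.0764) and the enteroendocrine call without descending control A2 (adjusted p = 0.0657). The colonocyte median was 0.17 without ascending control B1, the adipocyte median 0.36 without ascending control B2 and the enteroendocrine median 0.16 without ascending control B3. Proliferation genes were lower in the ascending colon, 21 of 25 past the threshold and 22 adjusted over the list alone (median -0.66, camera adjusted p = 7.26e-06, and adjusted p = 0.477 with an estimated correlation), with Mki67 at 21.2 ± 4.59 and 41.5 ± 8.44 FPKM. Stem cell (-0.66) and posterior patterning (-1.78) lists did not pass (adjusted p = 0.148 each). Both passed with median-of-ratios scaling (medians -0.52 and -1.69, adjusted p = 0.0427 each), and patterning passed with quantile normalization (-1.73, 0.0435). The other lists did not pass, namely cholesterol synthesis -0.38 (0.148), transmembrane mucins 0.36 (0.419), defence 0.31 (0.188), neutrophils -0.16 (0.554), macrophages 0.11 (0.300), unfolded protein response -0.01 (0.387), junctions -0.03 (0.634), ion transport -0.25 (0.574), circadian clock -0.26 (0.634), smooth muscle -1.12 (0.606), enteric neurons and glia -0.08 (0.986), fibroblasts -0.21 (0.634), endothelium -0.39 (0.328), blood 0.23 (0.634) and immediate early genes -0.04 (0.387). The median, mean and test of the unfolded protein, junction, neuronal, fibroblast and immediate early lists did not all have the same sign.

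limma called 4744 of 12515 genes between the regions, 1598 higher in the ascending and 3146 higher in the descending colon, 1044 of them by more than 2-fold on the log2(FPKM + 1) scale. The median of all genes lay at -0.14, and median-of-ratios scaling moved it to -0.01, with 4026 genes called, 2137 higher in the ascending and 1889 in the descending colon. Quantile normalization gave 1941 and 2262. With cage B left out 2069 genes passed, with cage C left out 2567 and with cage A left out 4582. Ascending control B1 and descending control A2 each lay toward the other region. Hoxa13, another gene of the hindgut's end, was 27.2 FPKM in ascending control B1, against a mean of 33.4 ± 8.14 in descending controls. Muc2 was 2136 and Hoxb13 44.5 FPKM in descending control A2. Without both, an alternative chosen after seeing the data, 5348 genes passed. The comparison was repeated in the 16 mutant libraries, a choice made after seeing the data: of 4677 genes called in controls and tested in mutants, 4668 (99.8%) had the same sign, and 3891 passed in that direction and 0 in the other.

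**Figure D4:**
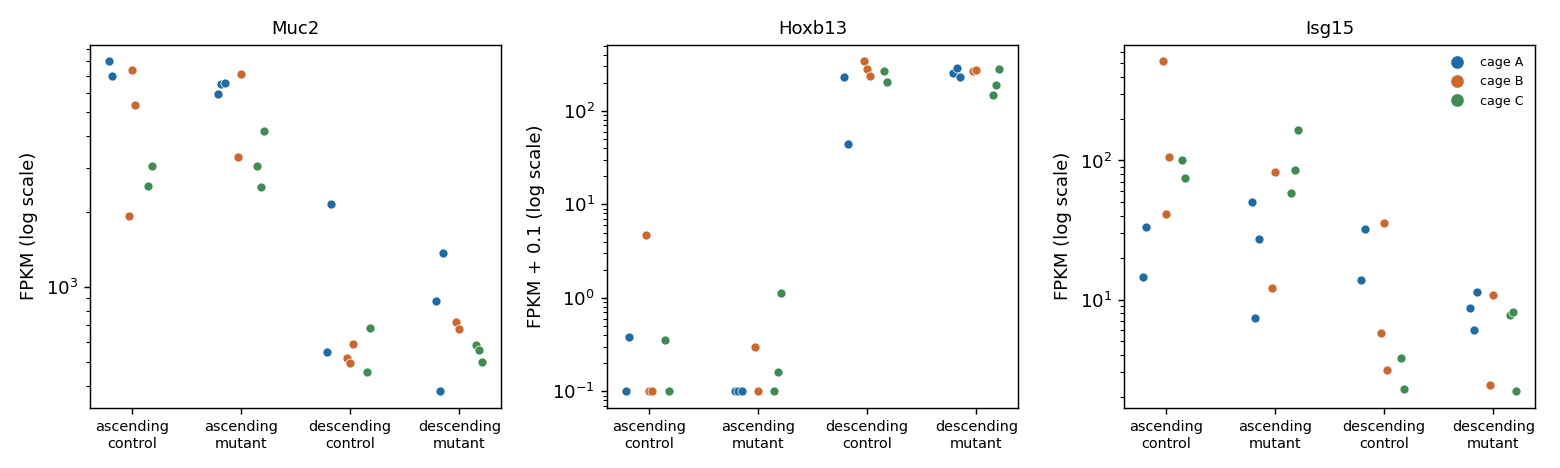
FPKM of Muc2, Hoxb13 (plus 0.1) and Isg15 in each library on log axes, by region and genotype, coloured by cage. Muc2 is 1923 FPKM in ascending control B1 and 2136 in descending control A2, between the levels of the other controls of the 2 regions, and Hoxb13 is 4.55 and 44.5 FPKM in these libraries.

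Genes whose mutant effect differed between cages were sought with an interaction of genotype and cage. In the descending colon limma called 1 of 12219 genes, the enolase gene Eno1b (adjusted p = 0.000336), with log2 differences of 0 in cage A, -3.37 in cage B and 0.75 in cage C, and 540 genes had an unadjusted p under 0.05. Eno1b is a near-identical copy of Eno1, so short reads are assigned between the copies with uncertainty. A difference of exactly 0 in cage A is also what a gene not detected there would give, so it need not be a measured lack of effect. Cage A bears another strain label as well, and cage and strain cannot be told apart for it. Gcnt1 was called as well with array quality weights (adjusted p = 0.0235), with differences of 0.29, -2.55 and -0.11 in cages A, B and C. In the ascending colon 0 of 12178 genes passed (lowest adjusted p 0.0641; 1264 at an unadjusted p under 0.05), and 1, Eno1b, passed with a pseudocount of 0.1. Its differences were 0, -3.47 and 0.53.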

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

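The tests of tissue position, of an exchanged region label, of mixed RNA, of other splits for the ascending fits without cage B and with array quality weights, and of the choice of 2 lists were chosen after the result was seen. Each gene or list score was searched, group by group, for a library whose gap to its nearest neighbour was large against the range of the group. Of 350 groups checked 37 gave such a library, where chance gives about 1 in 20, or 17.5. Descending control A2 accounted for 19 of them and ascending control B1 for 11.

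In descending control A2 the values lay toward the ascending colon. Its tuft cell score was 2.50, against 0.504 to 1.06 in the other 6 descending controls, and its posterior patterning score 2.91, against 4.06 to 4.24. Genes typical of the ascending colon were high in FPKM: Sptssb 13.6, Tmigd1 18.1, Fabp2 106, Apol10a 51.1, Prap1 1.75, Muc2 2136, Guca2a 1319.7 and Spdef 82.1. Genes typical of the descending colon were low: Sval1 17.2, Hoxb13 44.5, Hoxd13 0.38, Hoxd10 0.6, B3gnt7 85.4, Sycn 384, Cldn8 22.1 and Wfdc2 34.3. Zg16 was also low in it, at 62.6 FPKM against 543 to 1371 in the others.

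In ascending control B1 the values lay toward the descending colon, with Hoxb13 at 4.55 FPKM, Atp12a 2.39, Ly6g 6.73 and Sycn 299.8 above the other 6 ascending controls. Slc51a at 3.55, Slc10a2 at 1.64, Cyp4b1 at 9.82 and Gzmb at 1.65 were below them. Its bile acid handling score of 3.79 was below the others (4.87 to 5.34), whereas its colonocyte score of 7.81 was above them (6.38 to 6.97), with Fabp2 at 1006 FPKM.

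Single values stood apart in other libraries. Slc37a2 was 35.1 FPKM in ascending control B2, and Hoxa13 was 6.56 in ascending mutant C3, whose posterior patterning score was 2.61. The PPAR-alpha score was 4.38 in ascending mutant B1, the O-glycan extension score 4.29 in descending mutant A2, and the unfolded protein and junction scores were 3.92 and 5.81 in descending mutant C1, each the lowest of its group.

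Mutant effects on 12 lists differed between the regions by the interaction test, with medians (ascending minus descending effect) of -0.41 for T cells (many of them near the floor in the descending colon, where there is little room to fall), -0.43 for macrophages, -0.24 for interferon-gamma genes, -0.18 for enteroendocrine cells, -0.37 for posterior patterning, -0.40 for fibroblasts and -0.91 for blood. They were 0.14 for proliferation, 0.11 for cholesterol synthesis, 0.15 for PPAR-alpha, 0.15 for xenobiotic response and 0.20 for immediate early genes. No list kept its call with an estimated correlation, and 30 of 100 splits of the libraries gave as many lists (12 real, 18 at most in the others), so chance is not excluded for this count. The interaction had 198 genes at an unadjusted limma p under 0.05, and 85 of 100 splits gave as many (2577 at most, several times the real count, which points to a structure of the samples that was not identified).

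The first pattern weighed is the lower level of smooth muscle, fibroblast, neuronal, macrophage and T cell markers in ascending mutants, tested on log2(FPKM + 0.1), where effects are larger than on the log2(FPKM + 1) of the list medians (exact permutation p by list 0.129 for smooth muscle, 0.006 for fibroblasts, 0.018 for neurons, 0.008 for macrophages and 0.064 for T cells). A shallow sequencing of cage A alone would leave no effect in cages B and C, but the mean effect there was -0.93 (exact permutation p = 0.04). A single high control would leave none without ascending control B1, where it was -0.96 (exact permutation p = 0.00333). On log2(FPKM + 1), added after the result was seen, both were -0.64 (exact permutation p = 0.03 and 0.00167). The first test kept ascending control B1 and the second kept cage A, so the 2 causes acting together were not tested. In cage B without that library the effects on log2(FPKM + 1) were -0.24 for smooth muscle, -0.38 for fibroblasts and -0.37 for neurons. They were -0.10 for macrophages and -0.52 for T cells. A smaller share of non-epithelial tissue in the mutant pieces stays open, since the effects of the 5 lists, from -1.50 (neuronal, from only 2 members) to -0.51, had a spread of 0.37 that reassigned genotypes often reached (exact permutation p = 0.383, and spread 0.19 with exact permutation p = 0.608 on log2(FPKM + 1)). These tests used members with a mean of at least 1 FPKM, since the neuronal list had none at 2 FPKM, the minimum first intended, at which the other 4 lists gave -0.79 (exact permutation p = 0.03), -0.93 (exact permutation p = 0.00167) and a spread of 0.31 (exact permutation p = 0.566). A biological loss of these cells in mutants gives the same values and may equally account for them.

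The second pattern is the higher proliferation and cholesterol synthesis lists in ascending mutants, the 2 with the lowest camera p of 29. A larger epithelial share would raise 18 pan-epithelial markers as much, and their effect was 0.14 (exact permutation p = 0.057), 0.26 less than the 2 lists (exact permutation p = 0.034), which argues against that share as the whole of it over the 3 cages, but by cage the effect was 0.17, -0.07 and 0.32 in A, B and C, against 0.51, 0.36 and 0.34 for proliferation and 0.58, 0.27 and 0.37 for cholesterol synthesis, so cage C shows almost no gap. Tissue taken nearer to the descending colon would give a mutant effect that follows the regional difference with a slope near -0.6, and the lowest slope of the 3 cages was -0.018. In 1 of 100 splits, the real one, the medians were as large (proliferation 0.41 against 0.38 at most, cholesterol 0.40 against 0.36). The exact permutation p of the mean effects was 0.008 and 0.007 over 1000 arrangements. When the choice of 2 lists was repeated in every arrangement, 21 of 1000 gave 2 lists with a camera p as low (-log10 of the higher p 18.5, highest other 25.2). Such a result was therefore rare under reassigned genotypes. Chance is still not excluded, because the number of 2 lists was set after the result was seen. Neither list passed with an estimated correlation (camera adjusted p = 0.147). A response of the epithelium to the loss of the glycans is a candidate explanation that was not tested further.

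The third pattern is the position of descending control A2 and ascending control B1 between the regions. An exchanged region label would give a deviation with a slope near the full regional difference over 5368 genes, and the slopes were 0.372 and 0.157 (highest other control 0.0375). RNA mixed in from the other region, at the mean levels of its controls, would give every gene about the same foreign share. The third quartile of the share was 20.2 times the first in descending control A2 (1.57 and 31.8%) and 64.4 times in ascending control B1 (0.195 and 12.6%). Mixed-in RNA whose levels differed from those means could also spread the shares. The ratio was not computed for a known mixture, so mixing is not excluded. A piece taken from another position along the colon may account for both and was not tested, and the labels give no position within a region.

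Splits of the libraries within cages were counted for the other results: 100 of 1000 for genotype, 100 of 360 for region, and all 100 for cages A and C alone. For the ascending colon, 6 of 100 splits gave as many genes at an unadjusted limma p under 0.05 (1396 real, 3039 at most), so chance is not excluded, and the split with 3039 is the real one with ascending control B3 and mutant B1 exchanged. For the descending colon 65 splits gave as many (267 real, 4243 at most), so chance is not excluded, and the split with 4243, several times the real count, points to a structure of the samples that was not identified. That split is the real one with control B1 exchanged for mutant B2 and control C1 for mutant C1, and gave 890 genes past the adjusted threshold against 0. C1galt1 was 34.8 and 20.4 FPKM in control B1 and mutant B2, and 30.95 and 14.6 in control C1 and mutant C1, lower in the libraries labelled mutant. The O-glycan core score was lower in them too, at 3.66 against 3.91 in cage B and 3.51 against 3.87 in cage C. The other descending mutants, at 28.8 to 36.7 FPKM of C1galt1, lay within the range of the descending controls (28.0 to 38.7). These C1galt1 values therefore say little about the labels. For lists, 25 splits gave as many as the 14 of the ascending colon (18 at most) and 6 as many as the 14 of the descending colon (15 at most), so chance is excluded for neither. Without cage B 1 split, the real one, gave the 652 genes of the ascending colon (64 at most in the others). With array quality weights 2 splits gave 746 genes or more, the other being the exchange of ascending control B3 and mutant B1, with 1620. These alternatives were singled out because they gave calls, a choice that the splits do not repeat, so chance is left open for both counts. Chance is excluded for the 4744 genes between regions (1 split, 2887 at most).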

How the results depend on the processing

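The alternatives that leave out both ascending control B1 and descending control A2, and the list tests with each library left out, were chosen after seeing the data. The ascending count of 0 genes became 652 with cage B left out, 746 with array quality weights and 3 in the fit of all 30 libraries, and ranged from 0 to 170 with each library left out in turn, 170 being without ascending mutant B1. It stayed at 0 with a pseudocount of 0.1, no filter, a mean of at least 2 FPKM, median-of-ratios scaling, quantile normalization (lowest adjusted p 0.0562), robust moderation, cage A or C left out and no cage covariate. In the fit with array quality weights ascending mutant B1 and ascending control B1 had the lowest weights, 0.223 and 0.238. The cause was not tested for any of these. The 652 genes had a median size of 0.58 (log2) in cages A and C and of -0.11 in cage B in the same direction.

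The descending count of 0 became 1 with array quality weights (the cause was not tested), and was 0 with each library left out and under the other alternatives. The interaction gave 0 genes under every alternative. The count of 4744 genes between the regions became 2069 with cage B left out and 2567 with cage C left out, and was 4582 with cage A left out, and the cause was not tested. It ranged from 3860 to 5468 with each library left out, from 4001 to 6232 under the other alternatives, and was 5348 without both libraries. The cage-dependent count became 1 in the ascending colon with a pseudocount of 0.1, and 2 in the descending colon with array quality weights, and the cause was not tested for either.

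With an estimated correlation the lists passing fell from 14 to 0 in the ascending colon, from 14 to 0 in the descending colon, from 12 to 0 for the interaction and from 13 to 1 between regions, because a larger correlation within lists widens the test. With fry they were 5, 0, 0 and 19, and fry does not compare a list with other genes. With each library left out the ranges were 11 to 16, 10 to 15, 7 to 15 and 13 to 14, and without both libraries 16, 13, 11 and 14. Of 484 list medians under 4 alternatives 458 kept their side of the threshold, 15 no longer passed, 11 newly passed and 0 reversed. Of 508 values of named genes 507 kept theirs, 1 newly passed and 0 reversed.

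Libraries share replicate numbers, and with these as a replicate block 0 genes passed in the ascending colon, the descending colon and the interaction, and 4236 between the regions, so the block changed no call of 0 and moved the last count by less than 1.5 times. The numbers are not taken to pair the libraries, since not every pair correlated above 0.1. After the means of cage and genotype were removed, ascending and descending libraries of the same number correlated across genes at -0.26 to 0.36, above 0.1 in 4 of 15 pairs. Where a cage and genotype held only 2 libraries, their deviations were exact opposites, so both pairs gave the same correlation. The pairs are therefore not independent, and low correlations do not show that a number marks different animals. Controls and mutants of the same number correlated at -0.15 to 0.28 in the ascending and -0.18 to 0.38 in the descending colon, above 0.1 in 3 of 6 pairs each, the same 3 (B1, B2 and C2). The estimated depth limits genes near the floor, such as B3gnt6, and most in the 3 ascending mutants of cage A.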

Other observations

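The test of LXR targets was planned before its result was seen. The exchange of labels of 2 libraries was tested after the result was seen, Abca1 was chosen after its values were seen, and the values by cage were gathered after seeing the data.

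Cages differed in class II and clock genes across both genotypes, and cage A differs from the others in strain and age as well. Cages B and C share the strain label and differ in cage and age, so labelled strain does not account for differences between them. The class II gene H2-Aa was 233 ± 43.4 FPKM (SD, n = 5) in the ascending colon of cage A, 146 ± 115 in cage B and 9.90 ± 3.18 in cage C, and 158 ± 69.2, 219.7 ± 157 and 10.9 ± 4.45 in the descending colon. Cd74, the invariant chain, was 988 ± 216, 659 ± 394 and 72.8 ± 24.7 FPKM in the ascending colon, and Ciita, the class II transactivator, 4.92 ± 1.84, 3.98 ± 2.19 and 0.85 ± 0.319. The clock output gene Dbp was 2.33 ± 1.46, 9.70 ± 4.47 and 38.3 ± 19.1 FPKM in the ascending colon of cages A, B and C, and 1.66 ± 0.561, 15.4 ± 9.30 and 46.3 ± 42.7 in the descending colon. Arntl, which runs opposite to Dbp in the clock, was 9.76 ± 2.77, 7.86 ± 5.54 and 3.27 ± 2.11 in the ascending colon. Nr1d1 was 33.7 ± 13.3, 53.3 ± 37.2 and 87.5 ± 8.78.

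With genotype as a covariate, limma called 374 genes between cages C and A in the ascending colon (191 higher in C, 183 lower) and 137 in the descending colon (92 and 45), and 52 and 19 between cages B and A. Interferon-stimulated genes had a median log2 difference of 1.32 between cages C and A in the ascending colon, with 9 of 21 called higher (camera adjusted p = 5.28e-16, and adjusted p = 0.374 with an estimated correlation). In the descending colon their median was -0.38, the other way (adjusted p = 3.00e-04, and adjusted p = 0.475 with an estimated correlation). In the ascending colon proliferation genes had a median of -0.67, with 12 of 25 called lower (adjusted p = 3.03e-17, and adjusted p = 0.374 with an estimated correlation). Interferon-gamma and antigen presentation genes had a median of 0.04, with 1 of 24 called higher and 7 lower (adjusted p = 0.0327, and adjusted p = 0.884 with an estimated correlation), and in the descending colon of -0.86, with 7 of 21 called lower (adjusted p = 1.93e-18, and adjusted p = 0.109 with an estimated correlation). Clock genes had 7 of 15 higher and 2 lower in the ascending colon, with a median of 0.83 (adjusted p = 0.00240, and adjusted p = 0.374 with an estimated correlation).

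Abca1, a cholesterol exporter, was 5.38 ± 1.32 FPKM in ascending controls (SD, n = 7) and 2.83 ± 0.596 in ascending mutants (n = 8), a log2 difference of -0.77 (exact permutation p = 0.001, the smallest that 1000 arrangements can give; limma adjusted p = 0.212). In the descending colon it was 4.67 ± 2.03 and 3.18 ± 0.697 (-0.49, exact permutation p = 0.008). Lower activity of the nuclear receptor LXR may lower Abca1, and would lower its other targets. The mean effect of 10 other targets was -0.0738 in the ascending colon (exact permutation p = 0.357) and 0.0806 in the descending colon (exact permutation p = 0.728). The targets went both ways in the ascending colon, with Abcg5 (-0.87), Abcg8 (-0.63) and Abcg1 (-0.37) lower and Scd2 (0.80) and Srebf1 (0.21) higher, so their mean leaves the question open.

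More genes separated when ascending control B3 and ascending mutant B1 were exchanged (3039 against 1396 at an unadjusted limma p under 0.05). An exchange of their labels may be the cause. C1galt1 was 18.6 FPKM in mutant B1 and 36.3 in control B3, a log2 difference of -0.93, where an exchange would predict the reverse. However, the mean log2(FPKM + 1) of the whole O-glycan core list, which includes C1galt1, was also lower in mutant B1 (3.88 against 4.61). The low value is therefore not particular to C1galt1, and it argues only weakly against an exchange. The 652 genes called in cages A and C, signed by their change there, had a mean of -0.289 in mutant B1 and -0.0029 in control B3 (difference -0.286), the opposite of what the labels predict. B3gnt6 was near the floor in both, at 0.11 FPKM in control B3 and 0 in mutant B1, against 9.52 and 19.5 in ascending controls B1 and B2. It therefore does not tell the 2 libraries apart. C1galt1 and the 652 genes disagree, and neither reading is excluded, so the labels were kept as given.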
